A study of Drosophila melanogaster with 3 samples.

How the data were processed

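The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole Drosophila melanogaster at the prepupal stage, with males and females pooled. The animals carried CG8319 fused at its C terminus to a green fluorescent protein, and an anti-GFP antibody pulled down the fusion protein with the DNA bound to it. Per the labels, chromatin was sheared by sonication to 200 to 800 bp. The 3 samples form 1 group, and the labels number them as biological replicates 1, 2 and 3. No untagged or untreated group was analysed here, so no comparison between groups of samples was possible. The replicates come from the same transgenic line. The p-values below measure placement over peaks, genes or sequence windows, not spread between animals.

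The authors deposited peak lists in a 10-column peak format, and read counts were not analysed here. Depth per sample is therefore unknown, and no interval that needs it is given. Per the deposited text notes, each replicate's list was called from that replicate's alignment with a control. The pooled list was called from the 3 alignments together with a control. The optimal list was derived from the replicate lists and the pooled list by the irreproducible discovery rate (IDR), which ranks peaks by how well they repeat. The replicate and pooled lists hold peaks together with background, so their lower ranks are not calls. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is the deposited value of the authors' peak caller, and its scale differs between lists. It was used only to rank and describe peaks within a list. The deposited −log10 q-value reaches its ceiling in all 4410 optimal peaks, so peaks were not ranked by it.

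Lists exist for the genome builds dm6 and dm3, 5 lists per build. All positions here are dm6, counted from 1. The dm3 lists entered only the agreement between replicates, and no position was converted between builds. In dm6 each replicate list and the pooled list held 30000 peaks, and the optimal list held 4410. These 4410 are exactly the highest-signal peaks of the pooled list. The optimal peaks had a median width of 410 bp. The summit of 2 of them lay beyond the peak's end, and these were kept as given.

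Genes and transcription start sites came from the Ensembl gene annotation of the assembly BDGP6 (release 115), which has dm6 coordinates. Transposable elements were left out. On the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4 this gave 18164 genes, 13945 of them protein-coding, and 23998 start sites. miRNA genes were identified by symbol from the RefSeq gene table of the same assembly. Sequence came from the RefSeq genome of that assembly, whose arm lengths were checked against those in the RefSeq annotation.

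Replicates were compared by their 4410 highest-signal peaks, the length of the optimal list, with an overlap of 1 bp or more counted as shared. Chance came from 1000 circular shifts of peaks within each chromosome, a one-sided test whose smallest p is 0.001. A peak was called a promoter peak when its summit lay within 500 bp of a start site, and distal otherwise. Signal of promoter and distal peaks was compared with a two-sided permutation test of 100000 resamples, whose smallest p is 1e-05. Annotation features and peak counts per gene were compared with 200 shifts, two-sided for features, whose smallest p is 0.01. A gene was called bound when an optimal summit lay within 500 bp of any of its start sites. A peak between 2 divergent genes can thus count for both. Shares of genes carry 95% Wilson intervals, which cover counting over genes only.

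Bound shares were compared between chromosomes, and between each of 31 gene lists and all other protein-coding genes, with two-sided Fisher's exact tests. Lists of RNA genes were compared with all other genes. The Benjamini-Hochberg adjustment ran over the 2 chromosome comparisons and over the 31 lists, with a threshold of 0.05. The lists, tests and alternatives were fixed before the data were examined. Some symbols were afterwards replaced by current synonyms, before any list was tested: Eip71CD by MsrA, phm by phtm, SmG by SNRPG, Unc-89 by Obsc and rye by Taf12L. Duplicates (Hr46, torso) were dropped. The patterns for Cpr, Prp and Mst genes were limited to a following digit, which left out Cpr, Prps and MstProx.

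Sequence within 50 bp of each optimal summit (101 bp) was compared with windows of that width centred 300 bp to either side. The share of windows holding each of 2080 words of 6 bases, with both strands merged, was tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the words. A fixed set of 25 consensus motifs was tested the same way, adjusted over the 25.

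The genes named in the text follow a rule fixed before the data were examined. It takes the 25 promoter peaks of highest signal that lie among the top peaks of all 3 replicates, named by the gene with the nearest start site, and up to 4 members of each list with the highest signal. It adds the 5 distal peaks of highest signal, and CG8319, EcR, usp, br, Eip74EF, Eip75B, Hr3, ftz-f1, Hr39 and Eip93F in any case. Genes named for their number of peaks, and words of 8 bases, were chosen after their values were seen.

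The alternatives varied the number of top peaks, the overlap rule, the promoter window (200 or 1000 bp), the start sites used, the sequence window (25 or 100 bp), the word length (7) and the background windows. They also used stricter sets of peaks, the dm3 lists, and 2 of the 3 replicates. Alternatives chosen after seeing the data were the strongest summit per 1 kb, summit windows shuffled with their dinucleotide counts kept (5 shuffles per window), and 10000 random gene sets matched on the number of start sites in 4 classes.

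The calculations were tested on simulated data. For agreement between replicates, lists of 4410 peaks built to share 60% gave 59.7%, and 0 of 20 pairs of independent lists were called. For the promoter share, 4410 peaks built to give 39.8% gave 39.1%. For the signal difference, a planted log2 difference of 0.20 over 4410 peaks gave 0.22. For gene lists over 18164 genes, 150 of 150 lists of 50 or more genes planted at 50% bound were recovered, as were 78 of 150 lists of 20 to 24 genes planted at 40%. Of 1400 unchanged lists, 8 were called. For words, 1 of 2080 was called between shuffles of the same windows, and a word planted in 10% of windows ranked 1. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.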

Results

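The data are peak lists from ChIP-seq of a GFP-tagged CG8319 protein in whole Drosophila prepupae, the stage between larva and pupa at which the steroid hormone ecdysone drives metamorphosis. There was 1 group of 3 biological replicates. The question the data can answer is where in the genome the tagged protein was recovered, and how well the 3 replicates gave the same places. Each replicate list held 30000 ranked regions with a median signal of 10.5, 18.9 and 11.1 in replicates 1, 2 and 3. The thresholded optimal list held 4410 peaks, with a median signal of 145 and a highest signal of 1792. Signal is the authors' peak caller value, used here only to compare peaks within a list. Positions are dm6, and read depth is unknown.

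The strongest places were shared by all 3 replicates. The highest-signal peak lay 88 bp from the start site of CG14100 (FBgn0036889, 3L, 19590430 to 19590800), in intergenic sequence, with a signal of 1792 in the pooled list and of 356, 863 and 576 in replicates 1, 2 and 3. The next lay 20 bp from the start site of Ugalt, a UDP-galactose transporter (FBgn0024994, X, 2703688 to 2704079, intergenic), with a signal of 1769. The peak ranked 3 lay 68 bp from Axn (FBgn0026597), the Wnt pathway inhibitor Axin, and 126 bp from RpS28a (FBgn0039739), a ribosomal protein gene (3R, 30022594 to 30022956, intergenic). Its signal was 1679.5 in the pooled list and 355, 819 and 501 in the replicates. A peak in an intron of Mettl5 and CG42374 lay 82 bp from a start site of Max, the partner of the transcription factor Myc (FBgn0017578, 3L, 19264089 to 19264512, signal 1463). A peak in the 5′ UTR of Chro, which encodes the chromatin protein Chromator (FBgn0044324), lay at 3L, 22878710 to 22879085, with a signal of 1422.

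Further promoter peaks among the 25 strongest lay beside genes of several kinds. Genes for mitochondrial proteins included mRpL41 (FBgn0034001, 2R, 15217563 to 15217937, signal 1263, intergenic), mRpS10 (FBgn0038307, 3R, 15229350 to 15229718, 1140, intergenic) and PNPase, a polynucleotide phosphorylase (FBgn0039846, 3R, 31404495 to 31404832, 1101, 5′ UTR). Beside these stood Hsp27, a small heat shock protein (FBgn0001226, 3L, 9383726 to 9384096, 1196, intergenic), and larp, an RNA-binding protein (FBgn0261618, 3R, 28326405 to 28326804, 1212, intron). Others were gish, a casein kinase (FBgn0250823, 3R, 16280540 to 16280922, 969, intron), and scb, an integrin (FBgn0286785, 2R, 15248548 to 15248775, 906, intergenic). The rest of the 25 were CG1888, CG13921, CG31145, CG8320, CG13390, CG8360, Tcs5, CenG1A, GstE13, Pal1, Hpf1, the long non-coding RNA CR31044 and the antisense RNA CR45928, with signals from 917 to 1272. The 25 were chosen to lie among the top peaks of every replicate.

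The 5 strongest distal peaks had signals from 1279.6 to 1598. The strongest lay in an intron of ush, 1405 bp from the nearest start site, which belongs to cbt, a transcription factor gene (FBgn0043364, 2L, 480905 to 481301). The others lay in an intron of CG11050 (2L, 6612523 to 6612898), in intergenic sequence 11952 bp from CG13323 (2R, 13035102 to 13035527), in an intron of the kinase gene Lk6 (3R, 11760881 to 11761238), and in an exon of a long non-coding RNA inside osa (3R, 17704238 to 17704590). All 5 lay among the top peaks of each replicate.

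CG8319 itself, the gene encoding the tagged protein (FBgn0037722, 3R, 9627321 to 9628676), carried no optimal peak. The nearest optimal summit was 8795 bp away. Replicate 1 had 1 listed region overlapping the gene, at rank 6006 and a signal of 19.6, and replicates 2 and 3 had none. Within 20 kb of the gene lay 2 optimal summits, where even spacing over the chromosome arms would give 1.36.

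Replicates agreed far beyond chance in their strongest peaks. On average 76.0% ± 2.19 (SD over 3 pairs) of the 4410 strongest peaks of a replicate overlapped one in another, against 2.41% after circular shifts (permutation by shifts, one-sided p = 0.001, the smallest that 1000 shifts can give). The pairs gave 75.7% for replicates 1 and 2, 74.0% for 1 and 3, and 78.3% for 2 and 3. Of the 4410 optimal peaks, 2915 (66.1%) lay among the top peaks of all 3 replicates, 1033 of exactly 2, 441 of exactly 1 and 21 of none. Shifted lists gave a mean of 0.067 such peaks in all 3. The optimal list was itself derived from the replicate and pooled lists. A high count is thus partly built in, and the shifts do not measure it. The share found in all 3 was 99.5% in the tenth of peaks with the highest signal and 12.2% in the tenth with the lowest. Part of this gradient follows from comparing lists that end at the same rank, and 4330 of the 4410 overlap a listed region of any rank in all 3 replicates. With 2205 top peaks per replicate in place of 4410, 1596 optimal peaks were found in all 3.

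Peak strength ranked similarly in the 3 replicates. Spearman's rho across optimal peaks was 0.732 between replicates 1 and 2, 0.719 between 1 and 3, and 0.778 between 2 and 3, with a mean of 0.743 ± 0.0314 (SD, 3 pairs). These values run across peaks, which are not independent replicates, and describe agreement only.

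**Figure D1:**
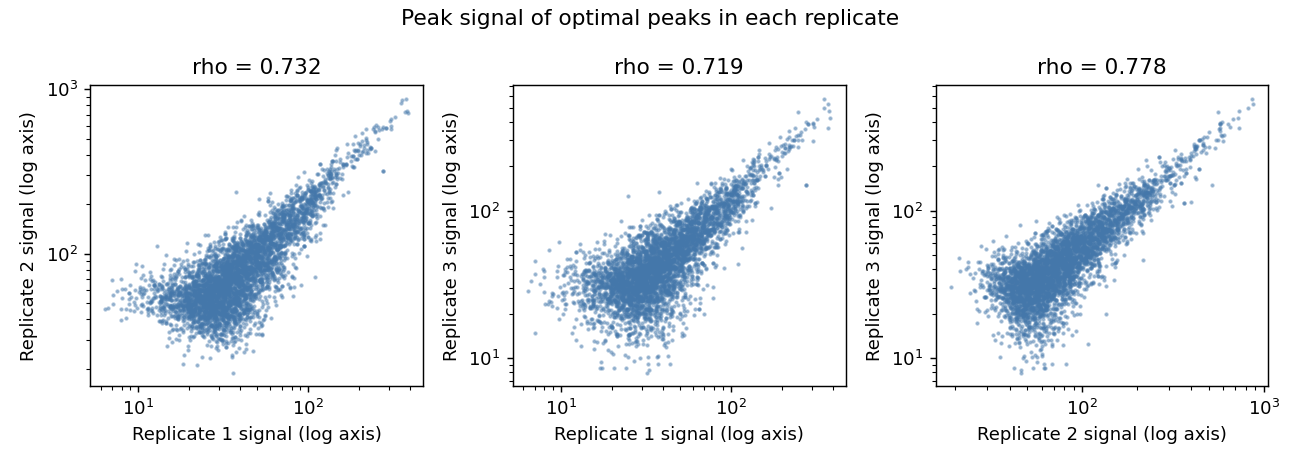
Signal of the strongest overlapping region in 2 replicates for each optimal peak, 1 point per peak, on log axes, with 1 panel per pair of replicates. Spearman's rho is 0.732, 0.719 and 0.778 from left to right, and the points spread more at low signal.

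Promoters held more optimal peaks than random placement gave. Summits lay within 500 bp of a start site in 1712 of 4410 peaks (38.8%, 95% Wilson interval 37.4 to 40.3), against 13.5% after circular shifts (highest of 1000 shifts 16.5%, one-sided permutation p = 0.001, the smallest possible). The same share among each replicate's 4410 top peaks was 40.7% ± 2.53 (SD, n = 3). Among the next 4410 peaks of each replicate it was 37.8%, 32.2% and 27.5% (32.5% ± 5.17, SD, n = 3), so the excess was not limited to the top ranks. In the 4410 lowest-signal peaks of the pooled list it was 16.1%. Within promoters most summits lay upstream of the start site. Of the 1712 promoter peaks, 1352 (79.0%) had the summit upstream of the nearest start site, and the median distance was 153 bp. Between 200 and 100 bp upstream there were 488 summits, where shifts gave a mean of 59.8.

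**Figure D2:**
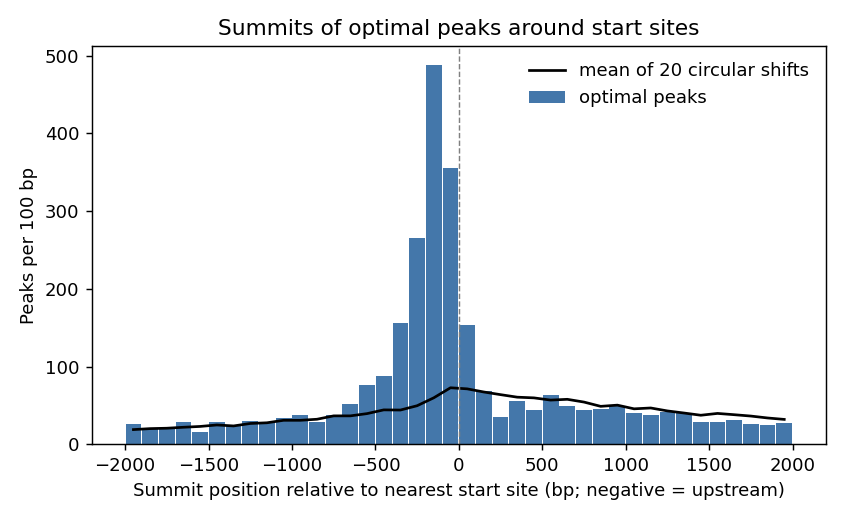
Number of optimal peak summits per 100 bp (bars) by position relative to the nearest start site in bp, negative values upstream, with the mean of 20 circular shifts (line). The highest bar, 488 summits, spans 200 to 100 bp upstream, and summits downstream of 200 bp lie near or under the line.

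Coding sequence held few summits. Only 34 peaks (0.771%) had a summit in coding exons, against 17.0% after shifts, and 55 (1.25%) had one in a 3′ UTR, against 4.93%. Introns held 2374 summits (53.8%, shifts 42.7%), intergenic sequence 1552 (35.2%, shifts 30.5%) and 5′ UTRs 276 (6.26%, shifts 3.04%). For each of these 5 classes the permutation p was 0.01, the smallest that 200 shifts can give (two-sided). Of the 2698 distal peaks, 1863 (69.1%) lay in introns, and 894 peaks lay more than 5000 bp from any start site.

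Promoter peaks were slightly stronger than distal ones. The median signal was 157 at promoters and 137 at distal sites, a log2 difference of 0.19 (p = 1e-05, the smallest possible, two-sided permutation test over peaks). Inside the replicates the difference was 0.23, 0.19 and 0.28 for replicates 1, 2 and 3, a mean of 0.23 ± 0.05 (SD, n = 3), with promoters higher in 3 of 3. The promoter share was 49.8% in the fifth of optimal peaks with the highest signal and 32.4% in the fifth with the lowest.

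Genes on the X chromosome were bound about as often as genes on the large autosomes. On X 335 of 2813 genes (11.9%) were bound, and on 2L, 2R, 3L and 3R together 1826 of 15233 (11.99%), with an adjusted p of 0.924 (Fisher's exact test, Benjamini-Hochberg over 2 comparisons, two-sided). On the small chromosome 4, 13 of 118 genes (11.02%, 95% Wilson interval 6.55 to 17.9) were bound, with an adjusted p of 0.924. The X comparison depended on the window. The X minus autosome difference was -1.29 percentage points within 200 bp (exact test, adjusted p = 0.0327) and 0.414 within 1000 bp (0.569). The adjusted p ranged from 0.0327 to 0.569 over its 5 alternatives.

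Of 13945 protein-coding genes, 1953 (14.0%) were bound, and 4 of the 31 fixed gene lists were bound more often than other genes while 8 were bound less often. Genes for cytoplasmic ribosomal proteins stood highest. In that list 52 of 92 genes (56.5%) were bound, against 13.7% of other genes (odds ratio 8.17, 95% interval 5.29 to 12.7, Fisher's exact test, adjusted p = 4.107e-20). The same share in the replicates' top peaks was 56.9% ± 7.63 (SD, n = 3). RpS28a had the highest signal through the peak it shares with Axn, followed by RpS27 (3R, 25247390 to 25247618, signal 445, 2 bp from the start site) and RpL32 (3R, 30046117 to 30046452, 361).

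Genes for insulator and promoter factors were bound in 7 of 14 cases (50%, odds ratio 6.16, interval 1.84 to 20.6, exact test, adjusted p = 0.00500; replicates 47.6% ± 4.12, SD, n = 3). They included Chro, the insulator protein gene Cp190 (3R, 15275228 to 15275410, signal 462), Trl, which encodes GAGA factor (3L, 14757132 to 14757268, 301, in the 5′ UTR), and M1BP, a zinc finger factor of housekeeping promoters (3R, 8731939 to 8732106, 239). Each of these 4 peaks lay among the top peaks of all 3 replicates.

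Ecdysone response genes were bound in 10 of 24 cases (41.7%, odds ratio 4.40, interval 1.75 to 10.7, exact test, adjusted p = 0.00330; replicates 45.8% ± 7.22, SD, n = 3). Sox14, an ecdysone-induced transcription factor gene, had the highest signal (2R, 23978398 to 23978728, signal 798, 242 bp from the start site). E23, an ABC transporter gene, followed (2L, 3354928 to 3355135, 497), then the nuclear receptor gene Eip75B (3L, 17999618 to 18000027, 337, 2 bp from an internal start site in an intron) and Eip63F-1 (3L, 3928488 to 3928897, 200.3). Eip93F (131), usp, a partner of the ecdysone receptor (169.8), EcR, the receptor gene itself (109), and Eip74EF (104) were bound at lower signal. The EcR peak lay among the top peaks of 1 replicate and the Eip74EF peak of 2. No optimal summit lay within 500 bp of a start site of br, Hr3, ftz-f1 or Hr39. Some members have many start sites, 9 in br and 7 in Eip75B. Among random genes matched on that number 26.1% were bound, and the list did not pass against them (permutation of gene sets, adjusted p = 0.263).

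Cell death and autophagy genes were bound in 9 of 23 cases (39.1%, odds ratio 3.96, interval 1.51 to 9.84, exact test, adjusted p = 0.00806), and in 34.8% in each of the 3 replicates' top peaks. Atg13 (3R, 8349290 to 8349560, signal 523), Atg17 (3R, 5669343 to 5669579, 381) and Atg2 (3L, 2773990 to 2774170, 334) act in autophagy, and hid (3L, 18185841 to 18185966, 379) is a death inducer. The hid peak lay among the top peaks of 2 replicates. The list no longer passed with the stronger 2205 peaks (odds ratio 3.09, exact test, adjusted p = 0.114) or with the 2915 peaks found in all replicates (3.32, adjusted p = 0.0589). Its 4 alternatives ranged from 0.0249 to 0.114.

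Chemoreceptor, cuticle protein, testis and cytochrome P450 genes were bound less often than other genes. None of 179 chemoreceptor genes was bound (95% Wilson upper bound 2.10%, exact test, adjusted p = 5.718e-11), nor any of 115 cuticle protein genes (upper bound 3.23%, adjusted p = 3.249e-07) or of 32 testis genes (upper bound 10.7%, adjusted p = 0.0457). Among cytochrome P450 genes 4 of 85 were bound (4.71%, exact test, adjusted p = 0.0311), with Cyp6u1 highest (2R, 6975013 to 6975193, signal 373, 5′ UTR). The calls for testis and P450 genes were lost with only the stronger 2205 peaks (exact test, adjusted p = 0.278 and 0.346), within 200 bp (0.230 and 0.0863) and with peaks found in all 3 replicates (0.178 and 0.176). They were also lost against genes matched on start sites (permutation of gene sets, adjusted p = 0.075 and 0.092). In the first 3 of these the share of testis genes stayed at 0 and the odds ratio of P450 genes lay between 0.242 and 0.404, against 0.302 with all optimal peaks. Over 4 alternatives these ranged from 0.0134 to 0.278 for testis and from 0.00462 to 0.346 for P450 genes. Histone genes were bound in 2 of 115 cases (1.74%, exact test, adjusted p = 4.197e-05), namely His2Av (208) and His3.3B (136), which lie outside the tandem histone cluster. The cluster's copies are near-identical, so reads there cannot be assigned to 1 copy and its share is uncertain.

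Small RNA genes were also called bound less often than other genes, of which 12.1% were bound. Their start site here is where the annotated RNA begins, which may not be a promoter, so the shares are not directly comparable. The counts were 12 of 290 tRNA genes (4.14%, exact test, adjusted p = 3.089e-05), 10 of 269 snoRNA genes (3.72%, adjusted p = 1.663e-05) and 4 of 260 miRNA genes (1.54%, adjusted p = 4.841e-09). Among them tRNA:Tyr-GTA-1-8 had a peak of signal 421, snoRNA:Or-CD11a one of 279, 490 bp from its start, and mir-275 one of 199. The tRNA and snoRNA peaks also lay within 500 bp of start sites of other genes. For the snoRNA peak these included a ribosomal protein gene and a translation factor gene. The snoRNA call was lost with a 1000 bp window (exact test, adjusted p = 0.830, range over 4 alternatives 4.706e-07 to 0.830). None of 32 snRNA genes was bound (Wilson upper bound 10.7%, exact test, adjusted p = 0.0656).

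**Figure D3:**
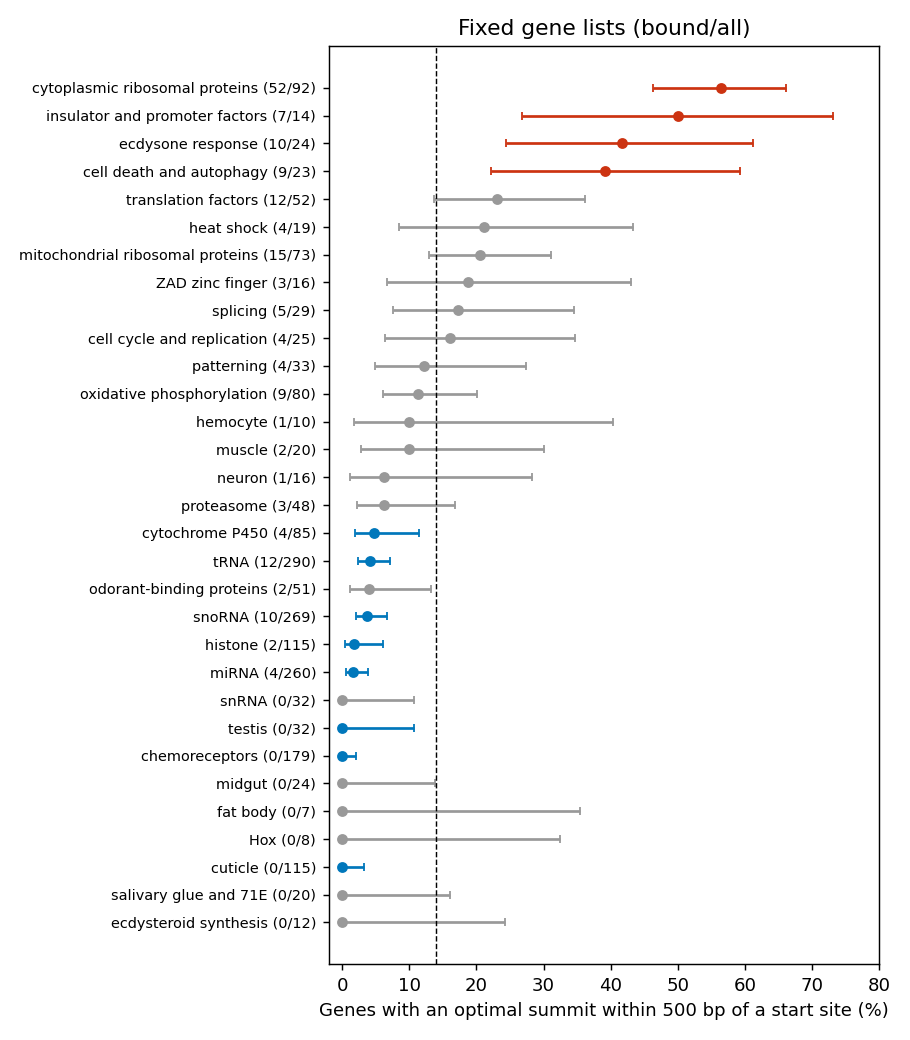
Share of each fixed gene list with an optimal summit within 500 bp of a start site, in percent, with 95% Wilson intervals over genes. Red marks lists bound more often and blue lists bound less often at an adjusted p under 0.05, and the dashed line is the 14.0% of all protein-coding genes. Cytoplasmic ribosomal proteins stand highest at 56.5%.

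The remaining lists did not pass the test. In simulations 78 of 150 lists of 20 to 24 genes planted at 40% were recovered, so for lists of that size a difference is not excluded. Genes for mitochondrial ribosomal proteins were bound in 15 of 73 cases (20.5%, exact test, adjusted p = 0.216), although mRpL41, mRpS10, mRpS23 and mRpL23 had signals from 889 to 1263. The mRpS23 peak is the one named above for CenG1A, whose start site is nearer. Translation factor genes were bound in 12 of 52 cases (23.1%), with eIF6 (927) and eIF2A (779) highest, splicing genes in 5 of 29, proteasome genes in 3 of 48 and oxidative phosphorylation genes in 9 of 80. The eIF6 peak is the one named above for the antisense RNA CR45928. Heat shock genes were bound in 4 of 19 cases, namely Hsp27, Hsp83 (333), Hsp26 (237) and Hsp22 (137). Cell cycle genes were bound in 4 of 25 cases, including Dp (451) and CycE (239.9), patterning genes in 4 of 33, including Doc3 (789) and tin (277), and ZAD zinc finger genes in 3 of 16. Muscle genes were bound in 2 of 20, odorant-binding protein genes in 2 of 51, neuron genes in 1 of 16 (elav, 540.0) and hemocyte genes in 1 of 10 (PPO3, 137). No gene was bound among 12 for ecdysteroid synthesis (Wilson upper bound 24.2%), 20 for salivary glue and the 71E cluster (16.1%), 8 Hox genes (32.4%), 7 fat body genes (35.4%) and 24 midgut genes (13.8%).

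Sequence at the summits was rich in A and T. The A or T content within 50 bp of optimal summits was 66.5%, against 55.0% in the flanks, a rise of 11.5 percentage points (95% bootstrap interval 11.1 to 11.9). The 6 chromosome arms held 57.8%. The flanks lay under that level, so part of the rise comes from the flanks and not from the summits. In the replicates' top peaks the rise was 10.6 ± 1.30 points (SD, n = 3). The rise was 10.3 points at promoter peaks and 12.3 at distal peaks. Of 2080 words of 6 bases, 589 were more frequent at summits than in flanks and 1061 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). All 20 of the most enriched words held only A and T. TTAAAA occurred in 32.7% of summit windows and 12.6% of flanks (exact test, adjusted p = 4.511e-156), and in 31.3% ± 1.42 of the replicates' top peaks (SD, n = 3). ATATTA occurred in 20.7% and 6.16%, and TTTAAA in 21.5% and 6.89%.

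**Figure D4:**
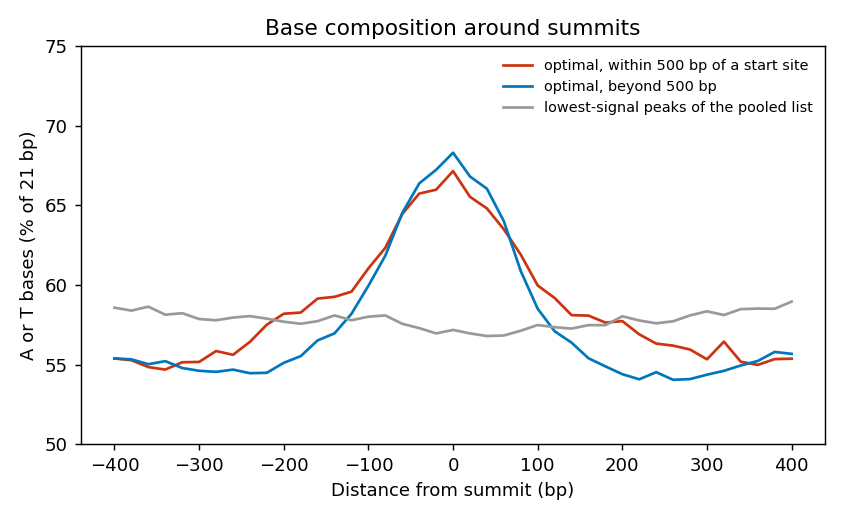
Share of A or T bases in 21 bp windows, in percent, by distance from the summit in bp, for optimal peaks within and beyond 500 bp of a start site and for the 4410 lowest-signal peaks of the pooled list. Both groups of optimal peaks rise to 67.1% and 68.3% at the summit, and the lowest-signal peaks stay at 57.2%.

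Each of the 25 consensus motifs was at most in a small part of the peaks. Only exact matches to the fixed strings were counted, so sites that differ from them, and factors outside the set, are not covered. The TATA box consensus occurred in 8.03% of summit windows and 3.02% of flanks (ratio 2.66, Fisher's exact test, adjusted p = 3.394e-34), but in 7.77% of shuffled windows with the same dinucleotides (adjusted p = 0.699). The control word TTAGGG also passed against flanks (2.79% against 1.78%, exact test, adjusted p = 4.858e-04) and not against shuffled windows (0.793), so a call against flanks alone is weak evidence. At promoter peaks the TATA box was more frequent than at promoters without a peak (8.41% against 5.61%, exact test, adjusted p = 0.00164). So was the control word (2.98% against 1.84%, 0.0418). Enriched against both flanks and shuffled windows were DREF (0.930% against 0.408%, exact test, adjusted p = 8.335e-04), CTCF (0.748% against 0.238%, 1.024e-04), Su(Hw) (0.794% against 0.261%, 1.024e-04) and BEAF-32 (12.6% against 11.1%, 0.0237). The BEAF-32 consensus searched was only CGATA, which lies within the DREF consensus TATCGATA, so these calls are not independent. Against promoters without a peak neither DREF (ratio 1.26, exact test, adjusted p = 0.480) nor BEAF-32 (0.969, 0.821) passed. The CTCF, DREF and BEAF-32 calls were lost with the stronger 2205 peaks (exact test, adjusted p = 0.690, 0.482 and 0.633). Over 7 alternatives the highest adjusted p was 0.770, 0.482 and 0.821 in that order, and 0.156 for Su(Hw), whose ratio there was 3 against 3.04 with flanks. Pita, GATA, Stat and Ohler motif 6 passed against flanks and not against shuffled windows. The Zw5 consensus was less frequent at summits (4.44% against 11.3%, exact test, adjusted p = 1.402e-41), as was that of GAGA factor (1.43% against 3.51%, 6.682e-12). Against shuffled windows (0.571%) GAGA factor was more frequent. The E-boxes CAGCTG (2.63% against 4.95%) and CACGTG (0.680% against 1.49%) were also less frequent than in flanks. Against shuffled windows CAGCTG was more frequent (1.35%, exact test, adjusted p = 3.280e-08), and the calls for Zw5 (0.116), CACGTG (0.208) and Ftz-f1 (0.0883) were lost. Ftz-f1 occurred in 0.136% against 0.385% (exact test, adjusted p = 0.0237). The EcR-Usp consensus occurred in 0 of 4410 windows (95% Wilson upper bound 0.0870%), against 0.0340% of flanks (exact test, adjusted p = 0.604). It is so rare in flanks that its absence at summits does not show depletion.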

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

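Alternatives chosen after the data were seen were the strongest summit per 1 kb, shuffled windows and matched gene sets. The others were fixed before the data were examined. Agreement, promoter share and the signal difference kept their direction and their side of the threshold under all alternatives run. The top of the pooled list equals the optimal list and repeats its value. Without 1 replicate, agreement ranged from 74.0% to 78.3%, and Spearman's rho from 0.719 to 0.778. These are the values of the single pairs given above, so they add no further check. With 2205 top peaks per replicate, 1596 optimal peaks were found in all 3, as fewer peaks enter. For X genes the difference was -1.29 points at 200 bp (exact test, adjusted p = 0.0327) and 0.414 at 1000 bp. For chromosome 4 it was -0.970 points with the settings of the report, 0.0843 at 200 bp, 2.18 over protein-coding genes, -3.40 at 1000 bp, -4.65 with the stronger 2205 peaks and -4.97 with peaks found in all 3 replicates. The chromosome 4 values did not pass the test, and the cause was not tested. Lists bound more often numbered 3 or 4, and less often 6 to 9, in all alternatives.

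Of the words of 6 bases, 589 were enriched and 1061 depleted. With words of 7 bases the counts were 1599 and 2946, as more words are tested. Against promoters without a peak they were 207 and 417, with only promoter peaks entering, and against shuffled windows 265 and 384. Only motifs that passed against flanks were followed. Against shuffled windows the ratio turned for GAGA factor (2.5), the string searched for Pita (0.828), Zw5 (1.16) and the E-box CAGCTG (1.95). Against promoters without a peak it turned for BEAF-32 (0.969) and Stat (0.871). The causes were not tested. Read depth is unknown, so no interval that needs it is given.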

Other observations

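The tests of position within promoters, of composition for single words, of shuffled windows, of matched gene sets and of words of 8 bases were chosen after the patterns were seen. For the X chromosome pattern, the share of peaks on X was already known when its test was set, and the share of copies was not.

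Some long genes held many optimal peaks. The highest counts were kirre with 19 (mean 13.7 in 200 circular shifts, highest 34) and sbb. The gene sbb (2R, 18278198 to 18357296) held 16, where shifts gave a mean of 2.29 and a highest value of 17. The transcription factor gene shn held 12 (mean 1.82, highest 14), ush, a GATA cofactor gene, 12 (mean 2.15, highest 14) and Eip75B 11 (mean 4.36, highest 28), so these counts lay within the range of the shifts. The kinase gene Raf held 11 (mean 1.60, highest 9) and tara 10 (mean 1.29, highest 9). These genes were chosen after their counts were seen. In all, 34 protein-coding genes held 8 or more peaks, where shifts gave a mean of 38.7. The shifts keep the spacing of peaks, and with it any clusters. This number therefore does not tell whether peaks cluster more than peaks placed singly at random.

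Sequence other than the AT-rich kind was also more frequent at summits. Against shuffled windows, words of 6 bases such as CAGTGC were enriched (6.64% against 2.64%, Fisher's exact test, adjusted p = 6.715e-32). Another was AGTGCA (8.89% against 4.72%, 3.341e-23). These were picked after their values were seen, and their shares in flanks are not given here. Words of 8 bases were compared with both flanks and shuffled windows. Of 32896 words of 8 bases, 175 were enriched at optimal summits against both, and 107 of these held 6 or more A or T bases. GGTCACCA occurred in 1.75% of summit windows, 0.170% of flanks and 0.0952% of shuffled windows (Fisher's exact test, adjusted p = 1.867e-20 against flanks), and in 1.43% ± 0.494 of the replicates' top peaks (SD, n = 3). The overlapping words GGGTCACC (1.38% against 0.113% of flanks) and CGGGGTCA (0.862% against 0.0907%) follow it. In the lowest-signal peaks of the pooled list GGTCACCA occurred in 0.227%. The M1BP consensus GGTCACAC shares its first 6 bases. It occurred in 0.612% of summit windows, and did not pass against flanks (0.363%, exact test, adjusted p = 0.0763) but passed against shuffled windows (0.0952%, 4.420e-09). At promoter peaks it was no more frequent than at promoters without a peak (0.993% against 1.17%, 0.821).

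Peaks with GGGTCACC lay on the X chromosome in 23 of 61 cases (37.7%), against 18.6% of other optimal peaks (adjusted p = 0.00493 over 12 words, Fisher's exact test). This word was singled out after its X share was seen. The overlapping words GGGGTCAC (39.2%, 0.00493) and CGGGGTCA (36.8%, 0.0413) also passed, while GGTCACCA (28.6%, 0.0918) and GTCACCAA (33.3%, 0.0918) did not. A candidate explanation is that GGGTCACC has more copies on X. Of its 2295 copies on the 6 chromosome arms, 23.1% lie on X (95% Wilson interval 21.4 to 24.8), under the interval of its peaks (26.6 to 50.3). By the rule set beforehand, copy number alone falls short of the share seen for this word. The word was picked for its X share, so the interval of its peaks may run high and copy number is not excluded. The copies also lie under the interval of the peaks for GGGGTCAC (22.8% of copies against 27.0 to 52.9), CGGGGTCA (20.7% against 23.4 to 52.7) and GTCACCAA (16.8% against 20.6 to 49.0). These words overlap GGGTCACC and are not independent of it. For GGTCACCA the copies (22.6% on X) lie inside the interval of its peaks (19.7 to 39.5). Copy number thus stays open as an explanation. The pattern rests on 61 peaks, and no biological explanation was tested.

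The AT-rich words at summits may follow in large part, but not alone, from base composition. The 20 most enriched words were 1.06 times as frequent (median, bootstrap interval 1.03 to 1.098) as in windows shuffled with their dinucleotide counts kept. This lay just within a bound of 1.1, set before the ratio was computed but after the AT-rich pattern was seen. Against the shuffled windows 11 of the 20 no longer passed, but 9 did, AAATAT most clearly (31.9% against 22.7%, exact test, adjusted p = 1.487e-33). The AT rise is not common to every region the peak caller listed. In the 4410 lowest-signal peaks of the pooled list the A or T content fell by 1.03 points at the summit, a ratio of -0.0897 to the rise of the optimal peaks. These lowest ranks hold background, so a base bias limited to regions of high signal stays open. Position within promoters was also set against it, since the rise at distal peaks was 1.20 times that at promoter peaks (interval 1.12 to 1.29). What stays open is whether the tagged protein prefers AT-rich DNA or open chromatin is AT-rich at its centre. No biological explanation was tested, as the design has 1 group.

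The lists bound more often could reflect genes with many start sites, or strong transcription that draws signal in any precipitation. Against random genes matched on the number of start sites, 3 of the 4 lists kept their call, and ecdysone response genes did not (26.1% bound among matched genes, permutation of gene sets, adjusted p = 0.263). The prediction set for strong transcription was that tRNA genes rise along with ribosomal protein genes. They did not, with an odds ratio of 0.314 (95% interval 0.160 to 0.558). That ratio was 0.0429 within 200 bp and 0.518 within 1000 bp, and how well reads map at tRNA genes was not examined. The tRNA genes therefore cannot decide the question for ribosomal protein genes. Oxidative phosphorylation genes had an odds ratio of 0.777 (0.341 to 1.56). Signal from a precipitation without the tagged protein was not analysed here. Places that any antibody recovers therefore stay open for the ribosomal protein genes, and equally for all 4410 optimal peaks. No biological explanation was tested.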
